A study of Mus musculus with 2 samples.

How the data were processed

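Single-cell RNA sequencing was measured in 2 libraries of mouse liver cells, 1 per group: CCl4, and CCl4 with IPA. Each group has 1 library, called replicate 1 by its order, and the number of animals behind it is not given in the sources used here. Per the labels' protocols, liver was dissociated with collagenase, red cells were lysed, dead cells were removed, and libraries were made with the 10x Genomics 3′ V3 chemistry and sequenced on an Illumina NovaSeq instrument. The deposited matrices hold unnormalised UMI counts per gene and barcode, made with Cell Ranger 7.1.0 per the file headers. Per the submitters' processing notes reads were aligned with Cell Ranger to mm9. Because 94.1% of the gene identifiers are in a GENCODE reference and the notes name another build, no coordinates are printed. Whether intronic reads were counted, and how barcodes were called as cells, is not given in the sources used here. The matrices list 55357 genes, of which 901 share a symbol with an earlier gene and were kept apart by identifier.

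Barcodes with at least 500 UMIs, at least 300 genes and under 20% mitochondrial UMIs (37 genes) were kept: 10294 of 10427 in the CCl4 library and 10459 of 10471 in the IPA library. Scrublet, run per library through scanpy, called 284 and 355 barcodes. These and clusters in which at least 20% of barcodes were called were left out as doublets, 377 and 405 barcodes in all. The analysed cells were 9917 and 10054, with 42041392 and 35405080 UMIs. Counts were log-normalised, and 2000 variable genes, 30 principal components and 20 nearest neighbours were used to build a shared-neighbour graph. Leiden clustering at resolution 1 was run on both libraries together without batch integration, and again within myeloid and within stromal or parenchymal cells, whose clusters are named cm and cs. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, with a random seed of 1.

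The groups, comparisons, 21 marker lists, 35 gene lists, cell filters, named-gene rule and most alternative settings were fixed before the data were examined. The limits that turn marker scores into names were not: they were adjusted over several rounds after the clusters had been seen. A cluster took the class with the highest mean log2 fold of its markers (pseudocount of 10 CPM) if that was at least 1.5 with at least 3 markers. Clusters closest to NK cells or innate lymphoid cells were taken as T cells where CD3 genes summed to at least 300 CPM. A name was withheld where the top 10 genes held as many markers of another class or 3 progenitor genes, where 8 or more marker lists reached the limit (called mixed), or where a shallow cluster had no marker among them. The lists of Kupffer cells and monocyte-derived macrophages were planned as separate classes and were merged as macrophage-like after the clusters had been seen, with the Kupffer-type cluster also given alone. The mixed cluster and unnamed clusters were counted in the denominators of shares and left out of expression.

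UMIs were summed over the cells of a class in each library and scaled to CPM, UMIs per 1000000 of the class. CPM has exact Poisson intervals, ratios have exact conditional binomial intervals, and shares have exact Clopper-Pearson intervals, at 95%. No test was run and no gene was called, since 1 library per group leaves no replicate error. A 0 was set at 3 UMIs over the class in that library to bound a fold, and no ratio is given where both libraries hold 3 or fewer. The same floor entered list medians, all-gene medians, percentiles and counts of members higher or lower. In stellate cell or fibroblast-like cells of the IPA library that floor is 70.0 CPM, so members without a UMI can count as higher. The UMIs behind each class set the precision: 1872526 and 1218131 in mononuclear phagocytes, and 768893 and 42830 in stellate cell or fibroblast-like cells.

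Named genes are the 12 highest and 12 lowest ratios in mononuclear phagocytes, 10 and 10 in stellate cell or fibroblast-like cells, and 4 and 4 in other classes with at least 100 cells in each library. They needed a CPM of 100 and 50 UMIs in the higher library. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor segment genes, gene models without a symbol, Xist, Y-linked genes and the markers naming the class were left out. Not every gene that this rule names is printed. Genes over 10 times higher in another class of both libraries were ranked apart as open to free RNA, and only classes with at least 50000 UMIs were used for this, a limit added after the data were seen. Members of gene lists named beyond the planned 2 to 4 per list, the lists given first, and the 4 genes given as shares of cells were chosen after their values had been seen.

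A gene list was measured where at least 4 members had 20 or more UMIs over both libraries. Its median log2 ratio was placed among 10000 random lists matched on expression in 20 bins, as a description of these libraries. Shares of cells with a UMI of a gene were taken after each cell had been thinned to 1000 UMIs at random. The calculations were tested on simulated data with 200 changed genes, drawn as Poisson counts of the class totals. The intervals assume such counts, and variation between cells or clusters was not simulated, so this checks the calculation only. There the intervals held the true ratio for 96.2% of 8446 genes in phagocytes and 98.0% of 5795 in stellate cell or fibroblast-like cells, and the direction was right for 98% and 97% of genes with a 2-fold change. This test was first run after the first run on the deposited data.

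Alternative settings were barcodes with at least 200 genes, mitochondrial UMIs under 10%, doublet calls kept, Leiden resolutions of 0.5 and 2, each library clustered alone, other scalings, a mean over cells, a mean of the monocyte and macrophage ratios, other count floors, and thinning to 2000 UMIs or none. Settings chosen after seeing the data were cells with at least 1000 UMIs, shares without the mixed cluster, CPM without Rn18s-rs5, Lars2, Mir6236 and mitochondrial genes, the clusters cm0 and cs1 alone, and lists without the genes that name the class.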

Results

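Droplet single-cell RNA sequencing was carried out on liver cells of mice in which carbon tetrachloride (CCl4), a hepatotoxin whose repeated dosing scars the liver, had induced fibrosis. There were 2 groups with 1 library each: CCl4 alone, and CCl4 with indole propionic acid (IPA), a tryptophan metabolite made by gut bacteria. According to its title, the study concerns IPA, profibrogenic macrophages and liver fibrosis. The CCl4 library held 10427 barcodes and 45009730 unique molecular identifiers (UMIs), with medians of 3172 UMIs and 1298 genes per barcode. The CCl4+IPA library (the IPA library from here on) held 10471 barcodes and 37983923 UMIs, with medians of 2771 UMIs and 1339 genes. After filtering and removal of doublets, 9917 and 10054 cells were analysed. The median share of mitochondrial UMIs was 3.53% in the CCl4 library and 1.78% in the IPA library. Intervals of shares, CPM and ratios are 95% exact intervals, and those of list medians are 95% ranges over 1000 Poisson draws. Both cover counting error only. With 1 library per group no difference has a replicate check, so each comparison is between these libraries and not between the treatments.

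The first comparison asked which cell types the livers yielded with and without IPA. Macrophage-like and conventional dendritic cell 2-like (cDC2-like) cells made up less of the IPA library, and natural killer (NK) or innate lymphoid cell 1 (ILC1)-like cells made up more of it. Macrophage-like cells were 158 of 9917 cells in the CCl4 library (1.59%, 1.36 to 1.86) and 20 of 10054 in the IPA library (0.199%, 0.122 to 0.307), an 8.01-fold higher share in the CCl4 library (5.01 to 13.5). The share of cDC2-like cells, which present antigen to CD4 T cells, was 3.47% (344 cells, 3.12 to 3.85) against 0.786% (79 cells, 0.623 to 0.978), 4.41-fold higher in the CCl4 library (3.45 to 5.71). Stellate cell or fibroblast-like cells, a class that takes in a smooth muscle-type cluster (cs1) with most of its cells, were 0.756% (75 cells, 0.595 to 0.947) against 0.229% (23 cells, 0.145 to 0.343), 3.31-fold higher in the CCl4 library (2.05 to 5.53). NK or ILC1-like cells were 5.62% (557 cells, 5.17 to 6.09) in the CCl4 library and 12.3% (1241 cells, 11.7 to 13) in the IPA library, a ratio of 2.20 (1.99 to 2.43).

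Monocyte-like cells differed by less than their counting error, at 2.14% (212 cells) and 1.93% (194 cells), a ratio of 0.903 (0.739 to 1.10). B cell-like cells were 37.7% and 32.7% (ratio 0.868, 0.828 to 0.909), T cell-like cells 23.9% and 28.8% (ratio 1.20, 1.14 to 1.27) and neutrophil-like cells 8.48% and 10.5% (ratio 1.24, 1.13 to 1.36). Plasmacytoid dendritic cell (pDC)-like cells were 4.02% and 3.65% (ratio 0.907, 0.785 to 1.05). Plasma cell-like (79 and 67 cells), basophil or mast cell-like (51 and 34), migratory dendritic cell-like (18 and 22) and hepatocyte-like cells (12 and 15) were few, and no cluster was named endothelial. These names come from clusters rebuilt for this comparison and marker lists fixed in advance. The log2 ratio of macrophage-like shares, -3.00 here, was -2.05 among barcodes with at least 200 genes and no other filter. That of cDC2-like cells, -2.14, was -1.35 when each library was clustered alone. For stellate cell or fibroblast-like cells it was -1.73, and -3.95 with mitochondrial UMIs held under 10%.

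Clusters left without a name made up 5.03% of the CCl4 library (499 cells) and 7.43% of the IPA library (747 cells), and thresholds adjusted after the clusters had been seen decided some of these. A cluster led by Ctla4, Il2ra and Foxp3, genes of regulatory T cells, held 1.54% and 3.23% of cells. A cycling cluster with Mki67 and Top2a among its leading genes held 1.18% and 2.23%. A granulocyte progenitor-type cluster, led by Camp and Ngp and with Prtn3, Elane and Mpo among its leading genes, held 0.655% and 0.656%. A dendritic cell-type cluster led by Ifitm3, Cd209a and Siglech held 0.625% and 0.179%, and another led by Mpeg1, Plbd1 and Ifi205 0.202% and 0.129%. Mesothelial-marker clusters led by C3, Saa3 and Dcn held 0.716% and 0.895% together (71 and 90 cells), and a cluster with biliary and hepatocyte genes 11 cells in each library. A cluster with markers of many classes, led by S100a8, S100a9 and Lyz2, held 5.68% of the CCl4 library (563 cells) and 0.0696% of the IPA library (7 cells).

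**Figure D1:**
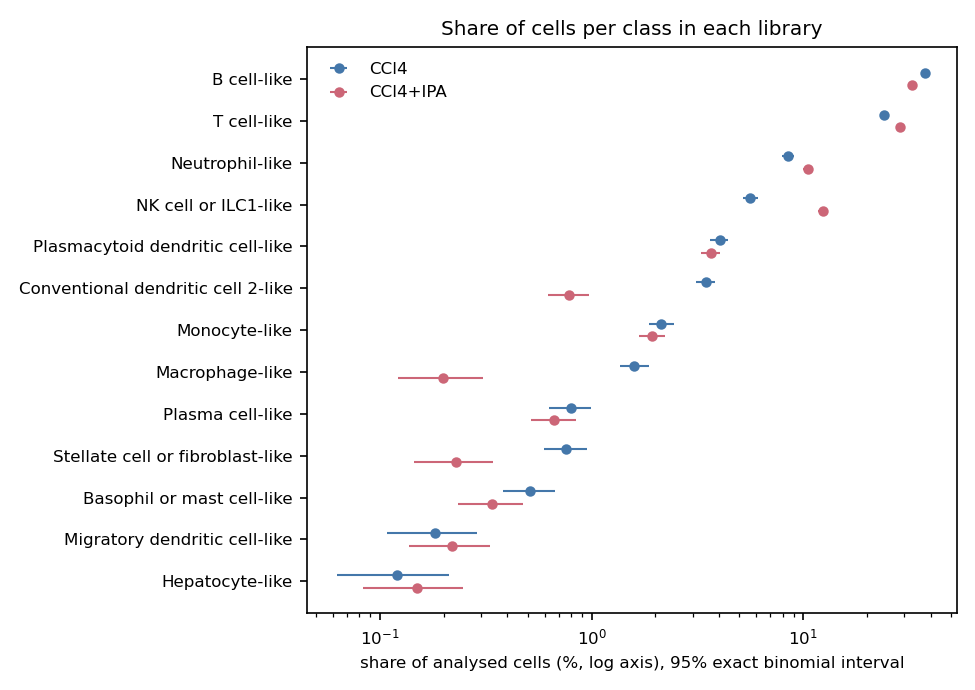
Share of analysed cells (%, log axis) in each named class for the CCl4 library and the CCl4+IPA library, with 95% exact binomial intervals (counting error only). Macrophage-like cells sit at 1.59% and 0.199%, and NK or ILC1-like cells at 5.62% and 12.3%.

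Cluster cm3 held most macrophage-like cells of the CCl4 library (117 of 158) and cluster cm11 most of those of the IPA library (11 of 20). Within the class, the difference lay in clusters expressing Trem2 and the complement genes C1qa, C1qb and C1qc. These clusters (cm3 and cm10) held 144 cells of the CCl4 library and 9 of the IPA library, a 16.2-fold higher share in the CCl4 library (8.31 to 36.2). A Kupffer-type cluster (cm11), led by Cd5l, Clec4f and Vsig4, genes of the liver's resident macrophages, held 14 and 11 cells, a ratio of 0.775 (0.318 to 1.84). Cluster cm3 was shallow, with a median of 967 UMIs in the CCl4 library, and 74 of its 117 cells there and 2 of its 6 in the IPA library had no mitochondrial UMI. The deeper cluster cm10, with a median of 6979 UMIs in the CCl4 library, held 27 and 3 cells. With 1 library per group, a cluster mostly of 1 library may be that library rather than a cell type.

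The second and main comparison asked how mononuclear phagocytes (monocyte-like and macrophage-like cells together, 370 and 214 cells with 1872526 and 1218131 UMIs) differed in expression. Thbs1 and a set of interferon-response genes were higher in the IPA library, while Apoe, Pf4, Hpgd and Hmox1 were lower. Thbs1 (ENSMUSG00000040152), encoding thrombospondin-1, a matrix glycoprotein that activates latent TGF-beta, was at 433 UMIs per 1000000 (CPM, 396 to 471) in the IPA library and 140.5 (124 to 158) in the CCl4 library, 3.08-fold higher (2.65 to 3.59). Apoe (ENSMUSG00000002985), the lipid carrier apolipoprotein E, was at 7777 CPM (7651 to 7905) in the CCl4 library and 2308 (2223 to 2395) in the IPA library, 3.37-fold lower (3.24 to 3.51). The median log2 ratio of all 8482 genes measured in this class was 0.17, and medians of gene lists are given less the all-gene median of their class, while counts of members higher or lower are of the ratios as they stand.

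The other genes with the highest ratios included Csrnp1 (3.07-fold, 2.31 to 4.11), Sbno2 (2.70, 2.27 to 3.23), Mfsd7a (2.59, 1.95 to 3.46), Ogfr (2.49, 1.91 to 3.26), Ms4a8a (2.48, 1.85 to 3.33) and Arid5a, an RNA-binding regulator of inflammatory transcripts (2.33, 1.79 to 3.04). Interferon-induced genes made up the rest: Stat2, a transducer of type I interferon signals (2.53, 2.00 to 3.20), the chemokine gene Cxcl10 (2.48, 2.03 to 3.05), Ifit3 (2.26, 1.72 to 3.0) and Oas3 (2.16, 1.69 to 2.77). In monocyte-like cells alone these ratios were 2.81 for Thbs1, 2.88 for Csrnp1, 2.53 for Stat2 and 2.15 for Cxcl10. Monocyte-like cells were themselves a mix: cluster cm0 held 163 and 177 cells, and cluster cm5, led by genes such as Ace, Ear2 and Adgre4 of nonclassical monocytes, 49 and 17, a 2.92-fold larger share of the CCl4 library (1.65 to 5.41). In cm0 alone the log2 ratios were 1.35 for Thbs1, 1.55 for Csrnp1, 1.30 for Stat2 and 0.98 for Cxcl10.

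Genes with the lowest ratios are given as the CCl4 value over the IPA value. Pf4, platelet factor 4, was 21.1-fold higher in the CCl4 library (9.54 to 58.3; 195 and 6 UMIs), Bcl2a1b, an anti-apoptotic gene, 3.09-fold (2.19 to 4.46), Lpl, lipoprotein lipase, 2.40-fold (1.95 to 2.98), and Ckb 1.96-fold (1.51 to 2.58). Hmox1, which degrades haem, was 2.20-fold higher there (1.74 to 2.82) and the metallothionein gene Mt1 1.94-fold (1.54 to 2.46). Apoe, Pf4 and Lpl are among the leading genes of cluster cm3, which held 117 and 6 cells. In monocyte-like cells alone the ratios were 1.46 for Apoe (1.38 to 1.54), 1.66 for Lpl (1.3 to 2.14) and 1.91 for Hmox1 (1.46 to 2.51), and in cm0 alone their log2 ratios (CCl4+IPA over CCl4) were -0.49, -0.70 and -0.74. Hpgd, which inactivates prostaglandins, was 6.58-fold higher in the CCl4 library (4.64 to 9.60) and 11.6-fold in monocyte-like cells alone (7.01 to 20.6). The remaining genes of this group were Rn18s-rs5, a copy of 18S ribosomal RNA (7.48-fold), Lars2 (4.29-fold), Mir6236 (3.55-fold) and the linker histone gene H1f4 (2.37-fold), and Rn18s-rs5 was lower in the IPA library in all 13 named classes. In macrophage-like cells alone, where different clusters held most cells of each library, Ccr2, a receptor of recruited monocytes, had 225 and 4 UMIs (7.88-fold lower, 3.03 to 29.2).

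**Figure D2:**
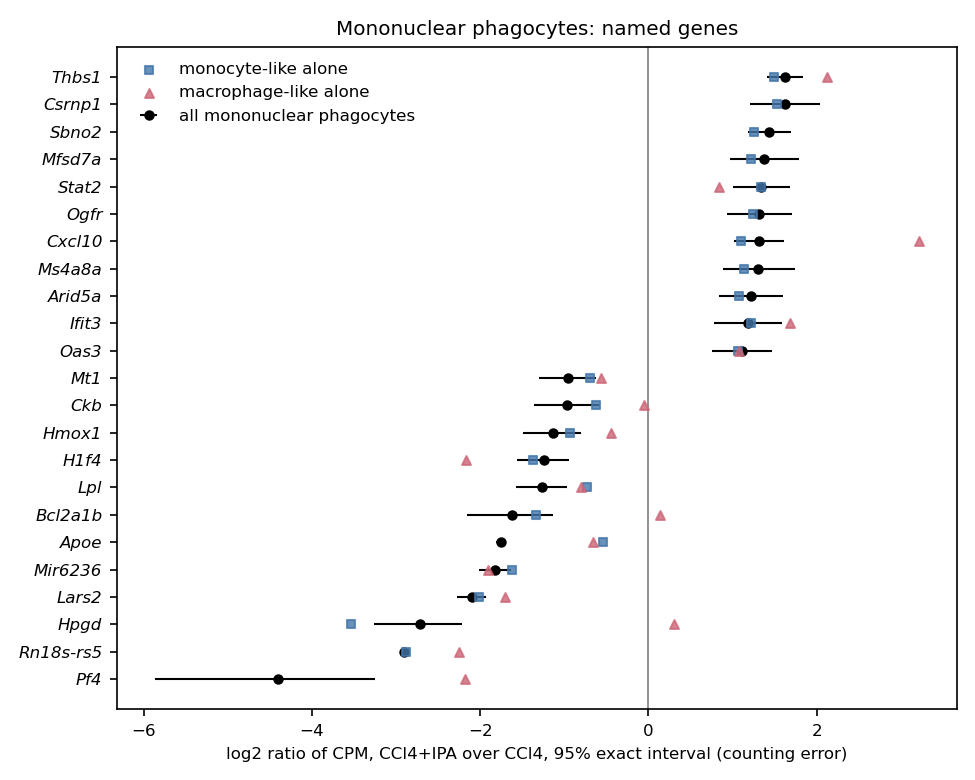
Log2 ratio of CPM (CCl4+IPA over CCl4) for named genes in all mononuclear phagocytes, with 95% exact intervals (counting error only), and in monocyte-like and macrophage-like cells alone where measured in both libraries. Thbs1 is highest, at a ratio of 3.08, and Pf4 lowest, 21.1-fold lower in the CCl4+IPA library.

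Scar-associated macrophage genes, the list closest to the study's question, were lower in the IPA library as a group. Of 13 measured members 12 were lower, and the list median was -1.98 (log2), at percentile 0 among 10000 random lists matched on expression. Macrophage-like cells were 158 of 370 phagocytes of the CCl4 library and 20 of 214 of the IPA library, so pooled values carry that difference in cell mix. Trem2 (ENSMUSG00000023992), a lipid-sensing receptor of scar-associated macrophages, was at 197 CPM (177 to 218) in the CCl4 library and 47.6 (36.2 to 61.6) in the IPA library, 4.13-fold lower (3.12 to 5.54). Gpnmb was 15.9-fold lower (8.23 to 35.2; 220 and 9 UMIs), Cd63 12.2-fold (6.28 to 27.2) and the fatty acid-binding protein gene Fabp5 4.20-fold (3.09 to 5.82). Spp1, osteopontin, had 89 UMIs and 1 UMI, a 57.9-fold ratio (10.1 to 2312), and Mmp12, macrophage elastase, had 39 and 0, at least 8.46-fold lower with the 0 set at 3 UMIs in that library. Capg was the member that was higher (1.23-fold, 1.06 to 1.43). Trem2, Gpnmb, Cd63, Fabp5 and Mmp12 also name the macrophage-like class, and without these 5 genes 7 of 8 members were lower, with a median of -0.87 before the all-gene median is taken off.

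In monocyte-like cells, whose share was alike in both libraries, the scar-associated list was lower too, with 8 of 10 members lower and a median of -0.54 (percentile 0). In other classes the list lay on the same side, at -0.38 in neutrophil-like, -0.35 in B cell-like, -0.25 in T cell-like, -0.13 in NK or ILC1-like and -0.06 in pDC-like cells. In monocyte-like cells Trem2 had 114 and 50 UMIs, 1.74-fold lower in the IPA library (1.24 to 2.47), and Cd9 63 and 22, 2.18-fold lower (1.32 to 3.72), while Ctsd differed by less than its counting error (ratio 1.03, 0.876 to 1.20). Within the largest monocyte cluster alone (cm0, 163 and 177 cells) the median was -0.18 before the all-gene median is taken off, a scale other than that of the -0.54. After each cell was thinned to 1000 UMIs, Trem2 was detected in 20.5% of phagocytes of the CCl4 library (61 of 298, 16.0 to 25.5) and 2.5% of the IPA library (5 of 200, 0.817 to 5.74). Gpnmb was detected in 9.40% (28 of 298, 6.33 to 13.3) and in 0 of 200, for which the exact interval of cells with a UMI at this depth reaches 1.83% and a floor of 3 cells is 1.5%. Thinning left out 72 phagocytes of the CCl4 library and 14 of the IPA library that were shallower, and without it the Trem2 shares were 43.8% and 17.3% and the Gpnmb shares 19.2% and 2.80%. All these shares are of the pooled class, so the larger part of macrophage-like cells in the CCl4 library enters them. Median depths of the thinned phagocytes had been 6156 and 6001.5 UMIs. In B cell-like cells (median 2797 and 2366 UMIs) the thinned Trem2 share was 0.109% and 0%, and in T cell-like cells (3913 and 3200 UMIs) 0.0432% and 0%. The Gpnmb shares were 0.0272% and 0.0317% in B cell-like and 0.216% and 0.0733% in T cell-like cells.

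Profibrogenic mediators did not move as a group, with 7 of 12 members higher in the IPA library, 5 lower, and a median of 0.08 (percentile 83.3). Thbs1 stood at the top of this list, followed by Osm, oncostatin M (2.01-fold, 1.69 to 2.39), Il1b (1.80, 1.67 to 1.94) and Fn1, fibronectin (1.55, 1.47 to 1.65). Igf1 was 5.95-fold lower in the IPA library (3.42 to 11.2) and Pdgfb, a mitogen of stellate cells, 3.55-fold lower (1.85 to 7.49). Tgfb1 was 1.23-fold higher (1.09 to 1.38), while Tnf (ratio 0.899, 0.586 to 1.36) and Ccl2 (0.811, 0.634 to 1.03) differed by less than counting error. The thinned share of phagocytes with a Thbs1 UMI was 8.72% (26 of 298, 5.78 to 12.5) and 21.0% (42 of 200, 15.6 to 27.3), or 16.5% and 40.7% without thinning. For Il1b these shares were 31.5% and 40.5% thinned, and 45.7% and 65.4% without. Background shares in thinned B cell-like cells were 0.0815% and 0.254% for Thbs1 and 1.49% and 2.41% for Il1b, and in T cell-like cells 0.173% and 0.293%, and 1.12% and 2.16%.

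All 20 interferon-response genes were higher in phagocytes of the IPA library, with a median of 0.63 (percentile 100). Gbp2 (2.57-fold, 1.80 to 3.70), Stat2, Ifit3 and Usp18 (2.19, 1.53 to 3.16) had the highest ratios and Isg20 the lowest (1.34, 0.907 to 1.96). In monocyte-like cells alone the median was 0.64 with 20 of 20 higher. Of the inflammatory cytokine and chemokine list 12 of 18 members were higher, with a median of 0.20 (percentile 98.3). Cxcl1 was highest, from few counts (7 and 25 UMIs, 5.49-fold, 2.31 to 15), and Cxcl16 (2.21-fold lower, 1.44 to 3.5) and Ccl5 (2.36-fold lower, 1.86 to 3.03) lowest. Ccl5 was over 10 times higher in another class of each library, so its UMIs here are open to free RNA. For genes of the NF-kB pathway and its feedback, 16 of 17 were higher, with a median of 0.28 (percentile 99.7), led by Birc3 (2.03-fold, 1.66 to 2.48), and Tlr4 was lower (1.83-fold, 1.01 to 3.47). Neither shift was particular to phagocytes: the inflammatory list lay at 0.56 in B, 0.38 in pDC and 0.32 in T cell-like cells, and the NF-kB list at 0.44 in pDC, 0.21 in NK or ILC1 and -0.11 in B cell-like cells. The immediate early and dissociation stress list was also higher in phagocytes (15 of 20, median 0.15, percentile 99.3). It stood at 0.034 in monocyte-like cells alone and 0.645 in macrophage-like cells alone.

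Complement and lipid-handling genes were lower over all phagocytes of the IPA library, and by less, or not, within each class. Of 11 complement genes 7 were lower (median -1.09, percentile 0), among them C3ar1 (8.46-fold, 4.14 to 20.1) and C1qb (2.79-fold, 2.42 to 3.23), whereas C3 was higher (1.60-fold, 1.41 to 1.83). Of 15 lipid-handling genes 13 were lower (median -0.94, percentile 0), such as Cd36 (3.02-fold, 1.68 to 5.83), the cholesterol exporter gene Abca1 (1.83-fold, 1.20 to 2.85) and its regulator Nr1h3 (2.35-fold, 1.44 to 4.02). Complement stood at 0.69 in macrophage-like cells alone (5 of 9 higher, C1qb 1.66-fold higher, 1.43 to 1.92) and at -0.32 in monocyte-like cells, and lipid handling at -0.21 and -0.62. In cluster cm0 alone these medians were 0.19 and 0.02 before the all-gene median is taken off. The 0.02 therefore does not show whether lipid-handling genes lay above or below all genes of cm0. Antigen-presenting MHC class II genes were lower over all phagocytes (6 of 7, median -0.68) but in neither class alone, with medians of 0.25 in macrophage-like cells (6 of 7 higher) and 0.56 in monocyte-like cells (7 of 7 higher). In monocyte-like cells H2-Eb1, a gene open to free RNA by the same limit, was 2.94-fold higher (2.33 to 3.73). That monocyte direction turned when doublet calls were kept (-0.77) or mitochondrial UMIs were held under 10% (-0.80), both before the all-gene median is taken off. Unfolded protein response genes were lower (8 of 12, median -0.56, percentile 0), for example Hspa5 (1.42-fold, 1.26 to 1.61), although Xbp1 was higher (1.63-fold, 1.39 to 1.91). Alternative activation genes were lower in 5 of 8 members (median -0.36, percentile 2.24), with Mrc1 3.44-fold lower (1.93 to 6.59), and glycolysis and oxidative phosphorylation had medians of -0.08 and -0.04.

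The third comparison asked about fibrosis in the stellate cell or fibroblast-like cells, of which there were 75 and 23 with 768893 and 42830 UMIs. Extracellular matrix genes were lower over this class of the IPA library (16 of 25 members, median -1.18, percentile 0), a direction that turned in cluster cs1 alone and when each cell counted equally, and that sets a collagen-rich cluster of the CCl4 library against mostly smooth muscle-type cells. In lists of this class, members without a UMI in the IPA library stood at 3 UMIs (70.0 CPM) and could count as higher. Fn1 was 7.68-fold lower (5.51 to 11), the small proteoglycan gene Dcn 4.90-fold (3.87 to 6.31), Col1a2 2.75-fold (2.19 to 3.51), Col3a1 2.66-fold (2.19 to 3.26) and Col1a1 1.60-fold (1.27 to 2.05). The basement membrane collagen genes Col4a1 (14.7-fold, 10.4 to 20.8) and Col4a2 (16.2-fold, 9.37 to 27.9) were higher in the IPA library. Dcn, Col1a1, Col1a2, Col3a1 and Lum name this class, and without these 5 genes 12 of 20 members were lower, with a median of -0.68 before the all-gene median is taken off. Over all analysed cells Col1a1 was at 59.5 CPM (2503 UMIs) and 7.74 CPM (274 UMIs), and Col3a1 at 147 CPM (6199 UMIs) and 18.3 CPM (649 UMIs). Lum (6.85 and 0.678 CPM), Lox (3.14 and 0.282), Col5a1 (7.73 and 1.13) and Fbn1 (10.8 and 1.84) were also several-fold lower in the IPA library over all cells. Dcn (286 and 208 CPM) and Col4a1 (5.92 and 5.82) differed less, and Eln (18.1 and 22.1) and Col14a1 (9.49 and 12) were higher in the IPA library.

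A smooth muscle-type cluster (cs1), led by Acta2, Tagln and Myh11, held most cells of this class in both libraries, 45 of 75 and 20 of 23. It was shallow, with medians of 969 and 840 UMIs, and 26 and 6 of these cells had no mitochondrial UMI. In it 6 marker lists reached the naming limit. A collagen-rich cluster (cs4), led by Dcn, Col3a1 and Saa3, held 30 and 3. Most UMIs of the class came from cs4 in the CCl4 library (702691 of 768893) and from cs1 in the IPA library (39407 of 42830). By the fixed rule, the genes with the lowest ratios were Trf (2083 and 2 UMIs, 58.0-fold, 16.0 to 479), the acute phase gene Saa3 (7057 and 7, 56.2-fold, 27.2 to 140), the monocyte chemoattractant gene Ccl2 (677 and 1, 37.7-fold, 6.75 to 1492), Nkain4 (388 and 1), Dmkn (362 and 1), Flrt2 (344 and 1), Gas1 (667 and 2), Cd44 (280 and 1) and Gda (526 and 2). Slpi had 955 and 0 UMIs, at least 17.7-fold lower in the IPA library with the 0 set at 3 UMIs. Highest were Fabp4 (17.6-fold, 13.5 to 23), Col4a1, Tagln (3.97, 3.04 to 5.11), Acta2, alpha smooth muscle actin (3.36, 2.60 to 4.30), Bgn (3.26, 2.66 to 3.98), Igfbp7 (2.76, 2.28 to 3.33), Cst3 (2.61), Myl6 (2.11), Apoe (1.96) and Itm2b (1.96). Endothelial genes were higher in this class of the IPA library (8 of 10 capillarization genes, median 2.88, percentile 100), with Pecam1 at 6 and 46 UMIs in cs1. Col4a1 and Col4a2 are in this list too, and which cells of cs1 carried them, or Fabp4, was not tested.

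Within cs1 alone the directions turned. The matrix median was 1.11 before the all-gene median is taken off (Col1a1 18 and 34 UMIs), Acta2 had 345 and 77 UMIs (log2 ratio -1.42) and Tagln 291 and 74 (-1.23). The stellate cell activation list, at 0.51 over the class with 9 of 17 members higher (percentile 98.9), was -0.96 in cs1 before the all-gene median is taken off. When each cell counted equally, the matrix median was 0.10 before the all-gene median is taken off, and the log2 ratio of Acta2 was -1.17. With 3 cells of the collagen-rich cluster in the IPA library, these values give no collagen level per fibroblast there.

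The remaining classes were described with up to 4 genes on each side. Neutrophil-like cells (841 and 1060) shared the interferon-response difference, with 18 of 19 members higher and a median of 0.69 (percentile 100). Ifit1 was 3.77-fold higher in the IPA library (3.16 to 4.52), Ifit3 3.11-fold (2.45 to 3.96) and Cmc2 2.64-fold (2.15 to 3.27), while Bst2 was 2.10-fold lower (1.56 to 2.85). Olfm4, a granule gene of a neutrophil subset, was 2.68-fold lower (2.13 to 3.39). In B, T and NK or ILC1-like cells the interferon list lay at 0.03, -0.10 and -0.04.

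In B cell-like cells (3734 and 3284) the 4 highest were Vps37b (2.11-fold, 1.99 to 2.24), Gpr132 (1.88, 1.69 to 2.08), Txndc11 (1.84, 1.66 to 2.03) and Nr4a1, an immediate early nuclear receptor (1.81, 1.76 to 1.87). The largest B cell-like cluster was c0 in the CCl4 library (1782 cells) and c4, with Cd83 and Ccr7 among its leading genes, in the IPA library (1207 cells), and these ratios are over all clusters. In T cell-like cells (2375 and 2894) they were Dgat1 (2.19, 1.96 to 2.44), Nr4a3 (2.08, 1.92 to 2.25), the pro-apoptotic gene Bcl2l11 (2.01, 1.88 to 2.16) and Vps37b (2.01, 1.94 to 2.08). NK or ILC1-like cells (557 and 1241) showed Ier5l (2.73, 2.24 to 3.33), Gpr132 (2.58, 2.14 to 3.12), Pgm2l1 (2.33, 1.89 to 2.88) and Nr4a3 (2.32, 2.06 to 2.61). In pDC-like cells (399 and 367) the highest were Iigp1, an interferon-induced GTPase (3.88, 3.11 to 4.89), Atf3 (3.69, 3.15 to 4.34), Nr4a1 (2.85, 2.52 to 3.22) and Vps37b (2.73, 2.23 to 3.35), and the heat shock gene Hspa1b was 2.18-fold lower (1.78 to 2.70). Rn18s-rs5 and Lars2 were among the 4 lowest in each of these 5 classes, 5.08 to 8.83-fold and 2.89 to 5.78-fold lower in the IPA library, as were Mir6236 in all but pDC-like cells and H1f4 in all but neutrophil-like cells.

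Transcripts of cell types outside a class differed between the libraries. Hepatocyte transcripts were higher in B and T cell-like cells of the IPA library (9 of 9 in each, medians 2.28 and 2.13), for example Apoa2 with 6 and 62 UMIs over B cell-like cells. Haemoglobin transcripts were lower there in T cell-like and pDC-like cells (medians -5.43 and -5.13), with 3579 and 60 Hbb-bs UMIs in T cell-like cells, and higher in neutrophil-like cells (2.60), with 92 and 514. In mononuclear phagocytes Hbb-bs had 65 and 4 UMIs (10.6-fold lower in the IPA library, 3.94 to 40) and Hba-a1 38 and 2 (12.4-fold lower, 3.19 to 106).

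**Figure D3:**
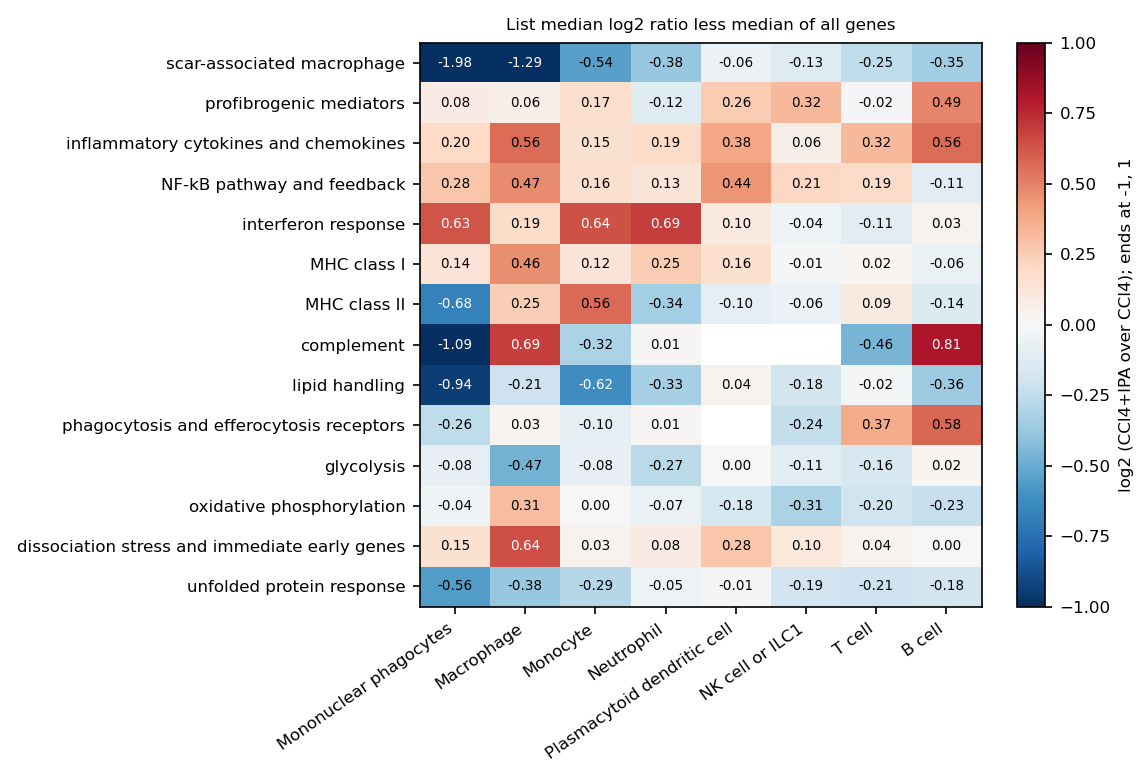
Median log2 ratio of CPM (CCl4+IPA over CCl4) of 14 gene lists in mononuclear phagocytes and 7 named classes, less the median of all genes of that class; blank cells had fewer than 4 measured members. The interferon-response list stands at 0.63 in phagocytes and 0.69 in neutrophil-like cells, and the scar-associated list at -1.98 and -0.38.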

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

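The clusters cm0 and cs1 taken alone, cells with at least 1000 UMIs, shares without the mixed cluster, CPM without ribosomal RNA-like and mitochondrial genes, and lists without class-naming genes were tests chosen after the results had been seen. No paired analysis was possible because each group has replicate 1 only, numbered by order and not by the labels. Values are log2 ratios (CCl4+IPA over CCl4) before any all-gene median is taken off, and unless said otherwise the cause was not tested. Of 71 recomputed class shares 65 stayed within the interval of the reported value, and none whose interval excluded 0 reversed. The others were macrophage-like cells at -2.05 among barcodes with at least 200 genes, stellate cell or fibroblast-like cells at -3.95 under 10% mitochondrial UMIs, NK or ILC1-like cells at 1.70 and cDC2-like cells at -1.35 with each library clustered alone, and, without the mixed cluster, B cell-like cells at -0.29 and T cell-like cells at 0.18, by a smaller denominator. Of 177 recomputed list medians 130 stayed within the interval, 41 moved, and 6 whose reported interval excluded 0 reversed. The scar-associated median in phagocytes stayed negative, at -2.14 with at least 200 genes, -0.18 in cm0, -1.12 as a mean of the monocyte and macrophage ratios, -1.27 with a floor of 100 UMIs and -0.87 without class-naming genes. The profibrogenic median was 0.053 without class-naming genes, and the inflammatory median 0.56 with at least 200 genes and 0.20 scaled by the median of the gene ratios. The interferon median in phagocytes was 0.68 without ribosomal RNA-like and mitochondrial genes, 0.63 scaled by the median ratio and 0.64 as a mean of the monocyte and macrophage ratios. Scaling by the median ratio is the same step as taking off the all-gene median. The 0.20 and 0.63 thus repeat values given above and are no separate check. In stellate cell or fibroblast-like cells the matrix median was -0.083 under 10% mitochondrial UMIs and reversed to 1.11 in cs1 and 0.10 as a mean over cells. The activation median, with a reported interval of -0.004 to 1.15 that holds 0, changed sign under 6 settings, to -1.05 with at least 200 genes, -0.22 under 10% mitochondrial UMIs, -0.98 at resolution 2, -0.96 in cs1, -0.94 as a mean over cells and -0.39 with a floor of 100 UMIs, and was 1.29 with at least 1000 UMIs. The class II median of monocyte-like cells reversed to -0.80 under 10% mitochondrial UMIs and -0.77 with doublet calls kept. On this scale the complement and lipid-handling medians of phagocytes reversed in cm0 as well, to 0.19 and 0.017. The all-gene median of cm0 was not taken off, so 0.017 does not place lipid-handling genes above all genes there. Of the 24 named phagocyte genes 13 were named again with a CPM floor of 50 and 6 with a floor of 300, since fewer or more genes then compete, and none of 309 single-gene values reversed. Of the 20 named fibroblast genes 10 were named again with at least 200 genes, 4 under 10% mitochondrial UMIs, 11 at resolution 2 and 4 in cs1, and 12 of 217 single-gene values reversed. With at least 200 genes, at resolution 2, in cs1 and as a mean over cells, Tagln was at -2.33, -2.18, -1.23 and -0.93 and Acta2 at -2.62, -2.48, -1.42 and -1.17. Igfbp7 was at -0.15 under 10% mitochondrial UMIs, Myl6 at -0.23 and Apoe at -1.07 in cs1, and Apoe at -0.27 as a mean over cells. The difference in thinned Trem2 shares was -12.1 points with doublet calls kept and -12.6 at resolution 2. Without thinning, which leaves deeper cells more UMIs, the differences were -26.5 for Trem2, -16.4 for Gpnmb, 24.2 for Thbs1 and 19.7 for Il1b. Fibroblast expression had no value with each library clustered alone, since the IPA library then had no cell in the class, and no ratio was computed where both libraries held 3 or fewer UMIs.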

Other observations

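IPA is a ligand of the aryl hydrocarbon and pregnane X receptors, so genes of both pathways were listed. The aryl hydrocarbon receptor list had 4 measured members in T cell-like and in stellate cell or fibroblast-like cells: Ahr itself, its partner Arnt, and Tiparp with Il22 in the former or Cyp1b1 in the latter. In T cell-like cells all 4 were higher in the IPA library (median 0.23 less that of all genes, percentile 93.1), and Cyp1a1, Cyp1b1 and Ahrr were too low to measure. In stellate cell or fibroblast-like cells 2 were higher and 2 lower (percentile 14.9), with Cyp1b1 at 246 and 5 UMIs (2.74-fold lower in the IPA library, 1.16 to 8.52). Most UMIs of that class came from cs4 in the CCl4 library and from cs1 in the IPA library. Its ratios therefore set unlike cells side by side. Il22, a cytokine made by type 3 lymphocytes, had 7 and 64 UMIs in T cell-like cells (9.23-fold, 4.23 to 23.9), Ahr was 1.44-fold higher (1.22 to 1.71) and Tiparp 1.29-fold (1.14 to 1.45). In mononuclear phagocytes Ahr had 130 and 150 UMIs (1.77-fold, 1.39 to 2.26). The pregnane X receptor list never had 4 measured members in a compared class, and its receptor gene Nr1i2 had no UMI in phagocytes of either library.

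Neutrophil-like cells of the IPA library were lower in a list that joins neutrophil maturity, granule and chemokine genes (10 of 14 members lower, median -0.42, percentile 0). The mix of clusters differed too: cluster c20, with Camp, Ngp, Lcn2 and Ltf among its leading genes, held 159 of 841 and 156 of 1060 cells of the class, and these values were not taken within a cluster. Camp was 1.32-fold lower (1.28 to 1.35), Lcn2 1.37-fold (1.33 to 1.41), and the chemokine genes Ccl3 and Cxcl2 1.60-fold (1.45 to 1.76) and 1.45-fold (1.40 to 1.49), while Csf3r (1.36-fold, 1.30 to 1.41) and Il1b (1.32-fold) were higher. Genes of naive lymphocytes were higher in T cell-like cells of the IPA library (10 of 10, median 0.30 less that of all genes, percentile 99.99), although Tcf7 and Il7r, at log2 ratios of 0.24 each, lay below the all-gene median of 0.27. The mix of T cell-like clusters differed as well, with cluster c10, led by Igfbp4, Lef1 and Tcf7, at 270 and 453 cells and cluster c17, led by Ccl5 and Gzma, at 240 and 202. The larger cluster c2, also led by Ccl5 and Gzma, held 760 of 2375 and 960 of 2894 cells. Cluster c7, led by Dapl1 and Lef1, held 376 and 489. The naive lymphocyte genes with the highest ratios were Ccr7 (1.91-fold, 1.80 to 2.03) and Satb1 (1.86-fold, 1.79 to 1.94). In NK or ILC1-like cells 12 of 12 activation and checkpoint genes were higher (median 0.28, percentile 99.5), among them Ctla4 (2.15-fold, 1.58 to 2.97) and Cd69 (1.49-fold, 1.40 to 1.60). Cluster c8 of this class, led by Xcl1 and Klrb1b, held 186 and 613 cells and cluster c5, led by Gzma, 371 and 628, so the mix of clusters differed here as well. In pDC-like cells the immediate early and dissociation stress list was higher (15 of 20, median 0.28, percentile 100), with Egr1 2.04-fold higher (1.82 to 2.28) and Hspa1a 2.60-fold lower (1.98 to 3.45).

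The tests of explanations that follow were chosen after the patterns had been seen. Those of library preparation, low-UMI fragments, yield of resident cells, scaling and shared free RNA were chosen after their own values had been seen as well, and those of free ribosomal RNA and of the mix of monocyte clusters (cm0 alone) before. The limits that decide them were set by judgement.

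The Trem2 and C1q macrophage clusters were a 16.2-fold larger share of the CCl4 library. Low-UMI fragments of macrophages are argued against as the whole cause, because among cells with at least 2000 UMIs and a mitochondrial UMI the ratio was 10.2 (3.20 to 52.1), from 33 and 3 cells. Most cm3 cells of the CCl4 library (median 967 UMIs, 74 of 117 without a mitochondrial UMI) fall outside this check. It therefore cannot tell whether the difference in cm3 came from such fragments. A lower yield of all resident cells alike in the IPA library is argued against by the pooled Kupffer-type, hepatocyte and mesothelial-marker clusters. Their ratio of shares (CCl4 over CCl4+IPA) was 0.848 (0.641 to 1.12). These clusters did not go one way: mesothelial-marker cluster cs0 held 12 and 51 cells and cs2 42 and 20, but the ratio of cs2, 2.13 (1.22 to 3.83), and that of the Kupffer-type cluster, 1.29 (0.544 to 3.14), also had upper limits under the 8.31 at which the interval of the macrophage clusters begins. Most of those 97 and 116 cells carried mesothelial markers, and fibroblast-like and cDC2-like cells were a smaller share of the IPA library too. Of the fibroblast-like clusters, left out of that pool, cs1 was at 2.28 (1.32 to 4.08). Cluster cs4, with 30 and 3 cells, was at 10.1 (3.15 to 51.9), which overlaps the interval of the macrophage clusters. A lower yield of only some resident cells is therefore not argued against. An effect of IPA on these macrophages, a difference between animals and a loss of these cells in 1 suspension stay open, and none was tested.

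Interferon-response genes were higher in monocyte-like cells of the IPA library. A shift of all genes by the scaling is argued against by the median less that of all genes, 0.638 (0.565 to 0.764). A different mix of monocyte clusters is argued against by the same difference within cm0, 0.544 (0.439 to 0.631). Free RNA shared by all droplets is argued against, since the highest such difference in B, T and NK cells was 0.033, although neutrophil-like cells stood at 0.69 and pDC-like cells at 0.10. An effect of IPA may remain as a hypothesis, but an interferon response of single animals was not tested and stays open as well.

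UMIs of Rn18s-rs5, the copy of 18S ribosomal RNA, were higher in the CCl4 library. The Rn18s-rs5 share of UMIs was 8.23% and 1.16% in B cell-like cells and 6.57% and 0.893% in monocyte-like cells. Free RNA at a level amount per droplet is argued against as the whole cause. The slope of log2 Rn18s-rs5 UMIs on log2 UMIs over depth deciles was 0.778, where such RNA would stay about level. It ranged from 0.710 to 0.910 over runs that left out 1 decile, which is not a 95% interval. A slope under 1 leaves a part from free RNA open, and free RNA that rises with droplet depth was not tested. Rn18s-rs5 was lower in the IPA library in 13 of 13 named classes, so a difference between library preparations and an effect of IPA on all cells cannot be told apart, because each group is 1 preparation. These tests cover Rn18s-rs5 only. The mitochondrial share of UMIs summed over a class was higher in the IPA library in stellate cell or fibroblast-like cells (2.21% and 3.41%). It was lower there in all other named classes, and no explanation of it was tested. As a median per cell it went the other way in stellate cell or fibroblast-like cells (1.53% and 0.405%). Medians per cell were higher in the IPA library in macrophage-like (0% and 0.0922%) and hepatocyte-like cells (0% and 0.00387%).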
